A study of Homo sapiens with 10 samples.

How the data were processed

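Total RNA from U2OS osteosarcoma cells was hybridised to Affymetrix exon arrays as biotin-labelled single-stranded cDNA, per the labels. The cells had been seeded at 25% density, grown for 30 h in medium with 10% serum, and then given PD0332991 or DMSO for 4 h, per the labels, which state a dose of 1 mM. That unit could not be checked against the arrays, and it is doubtful, since doses of this compound in culture are commonly micromolar. Per the labels each treatment has 5 biological replicates.

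The values are the log2 expression table the authors deposited, 1 value per gene-level probe set and array. The submitters' processing notes name RMA, Partek and the genome build hg18, without versions or parameters. RMA corrects background, normalizes between arrays and summarises probes on the log2 scale, which compresses fold changes of dim genes. The choice of core or extended probe sets is not given in the sources used here. The array medians lay within 6.95 to 7.06, but the interquartile ranges ran from 3.18 to 3.68, so the deposited log2 values were not identical in distribution between arrays. They were used as deposited in the main comparison. Signals over background and detection calls were not used here, so dim genes could not be set apart from background except by their mean level.

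Probe sets were named through the annotation of the array platform, with symbols checked through Entrez identifiers against a RefSeq gene table of assembly GRCh38.p14. This changed 0 symbols, and 28 single-symbol probe sets without a match kept the annotation's symbol. Older symbols in the gene lists were matched through the table's synonyms. Probe sets with several symbols (2408) or without a name (5140) entered the tests and counts and were not named. CDK4 and LMNB1, which the rule for named genes would have included, have no single-symbol probe set and are not reported here. For gene lists each gene was represented by its probe set with the highest mean, leaving 14232 genes; 532 of the 659 list members fixed were measured. No coordinates are given, because the gene table is of another build than hg18.

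Treatment was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, array set as a covariate), with Benjamini-Hochberg adjustment over 21980 probe sets and a threshold of 0.05. The array set was taken from the array names in the labels: set 1 holds replicates 1 to 3 and set 2 replicates 4 and 5 of both treatments, so it is balanced against treatment. Fold changes have 95% confidence intervals from the moderated fit. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over 19 lists; camera with an estimated correlation and fry were alternatives. Array means of each list were also compared by an exact permutation of treatment within array sets (120 assignments), and list medians were placed among 10000 random lists matched on size and on 20 bins of mean expression.

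The design, the 19 lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named 13 genes of interest, the 10 largest changes in each direction among single-symbol genes past the threshold with the same sign in both array sets, and up to 4 members of each list with the smallest p, the latter given as values where they did not pass. Further genes named outside this rule are marked as such. The alternatives covered the array set and replicate number in the model, renormalization, a filter on the dimmest 33.3% of probe sets, the probe sets tested, variance moderation, array weights, a minimum fold of 1.2, the kind of list test and leaving out each array. Alternatives added after the data were seen left out both arrays numbered 1, raised the threshold to 0.1, used cyclic loess, left out list members shared between lists or DDIT4, or combined an estimated correlation with renormalization, array weights, leaving out both arrays numbered 1 or leaving out each array.

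The procedure was tested on simulated data for this comparison with 21980 probe sets, 66 of them changed at each size. It recovered 25.8% of changes of 0.5 on the log2 scale, 75.8% of changes of 1 and 97.0% of changes of 2, with 3 false calls among 134. These shares hold for a table with 134 calls, where the adjustment is looser than in the real comparison with its 11. In the same simulation camera called the 1 list that was shifted and 0 of 18 that were not. The simulated noise was independent between probe sets, so these lists lacked the correlation between members that real lists can have. The simulation therefore cannot show how often camera calls unshifted lists of correlated genes. Figures were drawn with Matplotlib 3.10.9 under Python 3.11.15.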

Results

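Gene expression was measured on Affymetrix exon arrays, summarised per gene, in U2OS cells treated for 4 h with PD0332991 (palbociclib), an inhibitor of the cyclin D-dependent kinases CDK4 and CDK6, or with the solvent DMSO. U2OS is a human osteosarcoma line. The 10 arrays held 5 biological replicates of each treatment, and the array names in the labels divided them into a set of 6 (replicates 1 to 3 of both treatments) and a set of 4 (replicates 4 and 5 of both). The labels give the dose as 1 mM, a unit that could not be checked here and stands far above the micromolar doses common for this compound, so the printed dose is doubtful. The table held log2 values for 21980 probe sets, of which 14432 carried 1 gene symbol, 2408 carried several and 5140 were unnamed. The array medians lay between 6.95 and 7.06 on the log2 scale, and the number of arrays limits the precision of every value. The comparison asked which transcripts respond within hours to loss of cyclin D-dependent kinase activity, with the transcription factor FOXM1 and its targets as the genes named by the study's title.

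After 4 h of PD0332991, 9 genes were lower and 2 were higher than in DMSO (limma with array set as a covariate, adjusted p under 0.05). Of the 9 lower genes, 5 (E2F2, CCNE1, CCNE2, DTL and MCM10) are members of the E2F and G1/S replication list described below. CCNE2 and CCNE1 encode the E-type cyclins that activate CDK2. CCNE2 fell by 1.89 on the log2 scale, a 3.71-fold decrease with a 95% confidence interval of 2.74 to 5.03 (SE 0.20, n = 5 arrays per treatment, limma adjusted p = 0.00911). CCNE1 was 1.94-fold lower (1.67 to 2.25, limma adjusted p = 0.00911), at 10.16 ± 0.09 in DMSO and 9.20 ± 0.12 after treatment (log2, SD, n = 5). E2F2, a transcription factor of the E2F family, was 2.01-fold lower (1.76 to 2.29, limma adjusted p = 0.00289), and CDC25A, the phosphatase that activates CDK2, was 2.14-fold lower (1.80 to 2.54, limma adjusted p = 0.00911). DTL, the substrate receptor of the ubiquitin ligase that degrades CDT1, and MCM10, a replication initiation factor, were 2.22-fold and 1.70-fold lower, both at a limma adjusted p of 0.0499. The remaining 3 were FAM111B, which encodes a protein with a trypsin-like protease domain, the zinc finger gene ZNF367 and the transcription factor gene MYB. FAM111B fell 3.44-fold (2.56 to 4.62, limma adjusted p = 0.00997), ZNF367 1.73-fold (1.47 to 2.04) and MYB 1.70-fold (1.48 to 1.94). MYB was dim, with means of 5.96 in DMSO and 5.19 after treatment (log2), where the lower quartiles of the arrays ran from 5.05 to 5.44. It was not called with the dimmest probe sets left out, after quantile normalization or after cyclic loess. Apart from leaving out single arrays, MYB kept its call in 9 of the 14 alternatives that tested it.

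The higher genes were DDIT4 and SESN3. DDIT4 encodes a stress-induced inhibitor of the kinase mTORC1 and rose 2.43-fold (2.10 to 2.81, limma adjusted p = 0.00177), from 6.35 ± 0.18 to 7.63 ± 0.21 (log2, SD, n = 5). SESN3 encodes a sestrin, also known as an inhibitor of mTORC1 signalling, and rose 1.57-fold (1.37 to 1.80, limma adjusted p = 0.0499). For all 11 genes, each of the 5 treated arrays lay beyond every DMSO array of its own set. These genes were selected on the same arrays, so this order is no independent support. Chance gives such an order to 1.67% of genes, and 2.60% of the 14232 genes on single-symbol probe sets had it.

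**Figure D1:**
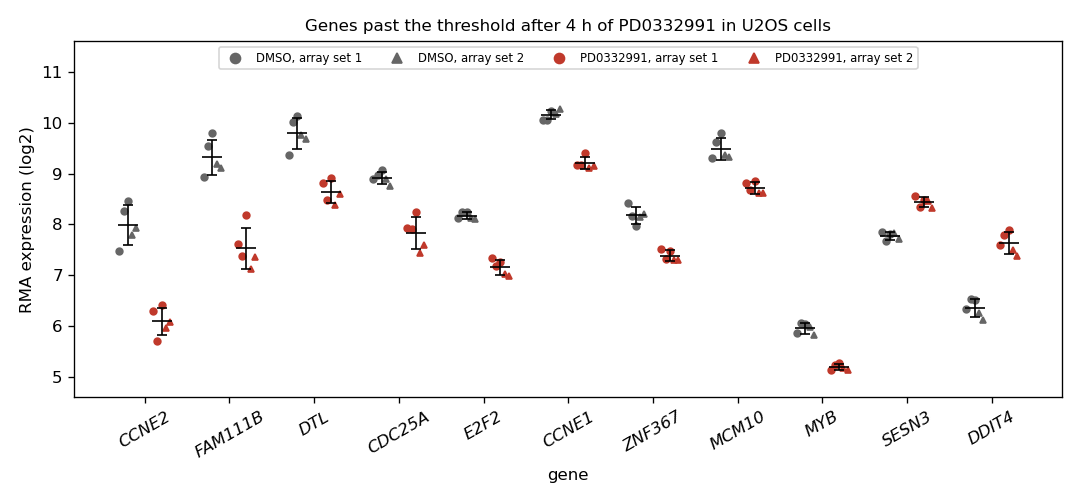
RMA expression on the log2 scale (vertical axis) of the 11 genes past the threshold (horizontal axis) on each array, DMSO in grey and PD0332991 in red, with circles for array set 1 and triangles for array set 2. Black bars give the mean and SD of 5 arrays. The treated arrays lie below the DMSO arrays for 9 genes, CCNE2 falling from a mean of 7.99 to 6.09, and above them for SESN3 and DDIT4.

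At an unadjusted p under 0.05, limma gave 311 probe sets as higher and 606 as lower. Together these are fewer than the 1099 that chance would give among 21980, so they are no sign of a broad response. No probe set with several symbols or without a name passed the adjusted threshold. SESN3, DTL, ZNF367 and MCM10 stood just inside it. When 1 array was left out, SESN3 kept its call without DMSO replicate 1 and lost it without any of the other 9 (limma adjusted p = 0.137 to 0.266), so that DDIT4 was then the 1 higher gene. DTL, MCM10 and MYB likewise kept their calls without DMSO replicate 1 alone, and ZNF367 without DMSO replicate 1 or 3. Fitted alone, the array sets passed no gene. At an unadjusted p under 0.05 limma gave 181 higher and 445 lower in set 1, and 560 and 710 in set 2. Chance would give 1099 in each set, both directions together. CCNE2 nevertheless changed by -1.92 in set 1 and -1.84 in set 2, E2F2 by -0.94 and -1.11, and DDIT4 by 1.30 and 1.25. The count of lower probe sets was 20 without DMSO replicate 1, not all of them single-symbol genes, and 5 without PD0332991 replicate 2 or 3. It was 1, E2F2, without any 1 of DMSO replicates 4 and 5 and PD0332991 replicates 1, 4 and 5. With replicate number as a block in place of array set, only DDIT4 and FAM111B kept their calls.

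Genes of the E2F and G1/S replication program moved together. Of the 61 measured members of this list, 59 were lower and 2 were higher, with a median log2 fold change of -0.34. E2F2, CCNE1, CCNE2, DTL and MCM10 passed the adjustment over all probe sets, and 31 members, all lower, passed when adjusted over the list alone. The list fell relative to other genes by limma's camera with a preset correlation (adjusted p = 3.0e-44, median -0.32 in array set 1 and -0.33 in array set 2). With an estimated correlation the adjusted p was 0.0547 on the deposited values, and it lay between 0.00700 and 0.0365 after quantile normalization, cyclic loess or array weighting or without both arrays numbered 1. With 1 array left out it was 0.0240 without DMSO replicate 1 and 0.0468 without PD0332991 replicate 3, and the call was lost in the other 8 fits (adjusted p = 0.0506 to 0.146). No list of 10000 random lists matched on size and expression level had as low a median, though random lists lack the correlation between members of a list. The mean of the list fell by 0.40 (95% confidence interval -0.60 to -0.21), and the exact 2-sided permutation test of array means within array sets gave p = 0.0167, the smallest that 120 assignments can give, or 0.106 after Benjamini-Hochberg adjustment over the 19 lists, where a value under 0.05 would need at least 7 lists at that smallest p.

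Genes of the FOXM1 and G2/M program did not pass as a group. Of 52 measured members, 22 were higher and 30 were lower, the median log2 fold change was -0.05, and no member passed, over all probe sets or adjusted over the list alone (camera adjusted p = 0.244, and adjusted p = 0.788 with an estimated correlation; exact permutation p = 0.633). Against 10000 random lists matched on size and expression level, however, its median stood at percentile 0.01, with 0.03 as the mean median of those lists. Random lists lack the correlation between members of a list, so this percentile can overstate a shift. The array means of the list changed by -0.03 with a 95% confidence interval of -0.23 to 0.16, so a shift of the group is not excluded. FOXM1 itself had a log2 fold change of -0.14 ± 0.10 (SE, n = 5, limma adjusted p = 1.00), PLK1 -0.18 ± 0.12 and CCNB1 0.10 ± 0.11. The members with the smallest p were SKP2 (-0.27), TROAP (-0.27), AURKB (-0.22) and GTSE1 (-0.22), none past the threshold. The treatment difference was larger in the E2F and G1/S list than in this one by -0.37 on the log2 scale (95% confidence interval -0.45 to -0.28, exact permutation p = 0.0167, the smallest possible). The G2/M list did pass, as lower, after quantile normalization (median -0.07, camera adjusted p = 0.0230), cyclic loess (-0.08, 0.00774) or array weighting (-0.11, 5.3e-08), and without DMSO replicate 1 (-0.07, 1.4e-04), PD0332991 replicate 3 (-0.10, 4.0e-04) or PD0332991 replicate 5 (-0.08, 0.00672). With an estimated correlation it passed in none of these 6 fits (adjusted p = 0.271 to 0.765). Its median was near 0 without PD0332991 replicate 4 (0.01, camera adjusted p = 0.699), DMSO replicate 2 (-0.02, 0.503) or DMSO replicate 3 (-0.02, 0.888), and -0.03 without PD0332991 replicate 1 (0.539). Over the 21 settings other than leaving out 1 array its adjusted p ran from 5.3e-08 to 0.921.

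**Figure D2:**
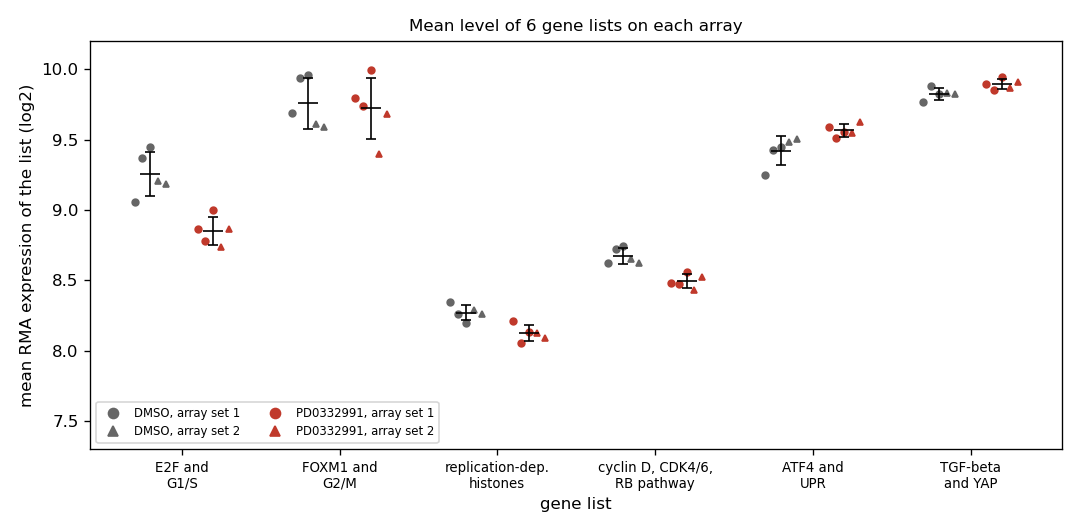
Mean RMA expression on the log2 scale (vertical axis) of 6 gene lists (horizontal axis) on each array, DMSO in grey and PD0332991 in red, circles for array set 1 and triangles for array set 2, with the mean and SD of 5 arrays in black. The E2F and G1/S means run from 9.06 to 9.45 on DMSO arrays and are lower on every treated array, with 8.74 as the lowest, while the G2/M means of the 2 treatments overlap.

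Replication-dependent histone genes, which are transcribed during S phase, were lower in 28 of 38 measured members, with a median log2 fold change of -0.15 (camera adjusted p = 0.00209, and adjusted p = 0.0547 with an estimated correlation). The exact permutation p of the array means was 0.0333, and no matched random list had as low a median. No histone gene passed alone, over all probe sets or over the list: H4C9 had -0.74 ± 0.18, H3C10 -0.38 ± 0.11, H4C1 -0.30 ± 0.12 and H2AC6 -0.25 ± 0.12 (SE, n = 5). These genes are near-identical copies whose probes can read each other, and their transcripts lack a poly(A) tail. In array set 1 alone the list did not pass (camera adjusted p = 0.0643, within a range of 1.7e-05 to 0.0643 over the 21 other settings).

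Among 26 measured components of the cyclin D, CDK4/6 and RB pathway, 15 were lower and 11 higher, with a median of -0.06. E2F2, CCNE1 and CCNE2 passed over all probe sets. Adjusted over the list alone, RBL1, which encodes an RB relative and is named here after its value was seen, joined the lower genes (-0.48) and CCND2, a D-type cyclin, was higher (0.59, 1.51-fold, limma adjusted p = 0.265 over all probe sets). The other components held values that did not pass: CCND1 0.22, CDK6 0.25, RB1 -0.15, E2F1 -0.21, MYBL2 -0.06 and, for the CDK inhibitor gene CDKN1A, -0.24. The list as a whole fell (camera adjusted p = 0.00856, adjusted p = 0.0547 with an estimated correlation, exact permutation p = 0.0167, percentile 0.91 of the matched random lists), but not without the members it shares with other lists (median 0.01, camera adjusted p = 0.683). It was not past the threshold in array set 2 alone (0.0980), without DMSO replicate 3 (0.0871) or without PD0332991 replicate 4 (0.0686); over the 21 other settings its adjusted p ran from 1.2e-04 to 0.683. Its median was -0.10 without DMSO replicate 3 and -0.04 without PD0332991 replicate 2.

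Genes of the ATF4 and unfolded protein response, which cells raise under amino acid or endoplasmic reticulum stress, passed as higher by camera with the preset correlation. Of 29 measured members, 23 were higher, with a median log2 fold change of 0.07 and a camera adjusted p of 2.3e-05 (adjusted p = 0.0547 with an estimated correlation, exact permutation p = 0.0167). The median stood at percentile 96.0 of the matched random lists, below that of the reference genes, a control list without a call (median 0.12, percentile 98.15). Without PD0332991 replicate 4 the ATF4 list had a median of 0.12 (camera adjusted p = 7.4e-06, and 0.146 with an estimated correlation). With an estimated correlation it passed in 0 of the 10 fits that left out 1 array. DDIT4 was the only member past the threshold, over all probe sets and over the list alone. Without it the list still passed by camera with the preset correlation (adjusted p = 0.00114). An estimated correlation was not run without DDIT4. HERPUD1, a component of endoplasmic reticulum-associated degradation, had a log2 fold change of 0.34 ± 0.10, CHAC1 0.39 ± 0.15 and XBP1 0.29 ± 0.11 (SE, n = 5), while ATF4 itself, named here after its value was seen, had -0.19 ± 0.11. In array set 2 alone the median was 0.03 and the list did not pass (camera adjusted p = 0.0980, within 8.9e-06 to 0.160 over the 21 other settings). DMSO replicate 1 had the lowest mean of this list, 9.24 against 9.43 to 9.51 on the other DMSO arrays.

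TGF-beta and YAP targets were higher in 17 of 24 measured members, median 0.07 (camera adjusted p = 0.00894, adjusted p = 0.0562 with an estimated correlation, exact permutation p = 0.0333, percentile 90.1 of the matched random lists). No member passed, among them SKIL at 0.38, CCN1 at 0.18 and PMEPA1 at 0.19. This list lost its call after quantile normalization (camera adjusted p = 0.142) or cyclic loess (0.263), with array weights (0.105), in array set 2 alone (0.199) and without PD0332991 replicate 3 (0.0798); over the 21 other settings the adjusted p ran from 0.00435 to 0.481.

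The other 13 lists gave no call by camera, and none of their genes passed over all probe sets. Their medians stood between percentiles 21.3 and 98.2 of the matched random lists, with the reference genes highest. Of 26 measured p53 targets, 16 were higher (median 0.03, camera adjusted p = 0.244). TP53INP1, at 0.47 ± 0.11, passed adjusted over the list alone, and SESN2, at 0.21, and POLH, at -0.30, did not. Senescence secretory genes were higher in 19 of 35 measured members, with a median of 0.01 (camera adjusted p = 0.213); IGFBP5 had 0.25, MMP14 0.21 and TNFRSF11B 0.21. This list passed as higher without DMSO replicate 1 (median 0.07, camera adjusted p = 0.00382, and adjusted p = 0.106 with an estimated correlation). For immediate early and ERK feedback genes (33 measured, 15 higher) the median was -0.03 and the mean -0.01 although camera pointed upward (adjusted p = 0.872), with KLF6 at 0.29 and FOSL1 at -0.38. Interferon-induced genes (35 measured, 16 higher) had a median of -0.03, against a mean of 0.00 and an upward camera direction (adjusted p = 0.496), with SAMD9 at 0.43 and IRF1 at -0.34. Lysosome and TFEB genes (32 measured, 15 higher, median -0.01, mean 0.02, camera upward, adjusted p = 0.496) and hypoxia and glycolysis genes (23 measured, 9 higher, median -0.01, mean 0.02, camera upward, adjusted p = 0.743) differed in sign in the same way; UVRAG was at -0.28 and BNIP3 at 0.41. Medians were 0.05 for cholesterol synthesis and SREBP2 genes (12 of 17 higher, camera adjusted p = 0.244, MSMO1 0.29), 0.01 for heat shock genes (7 of 14 higher, 0.496, HSP90AA1 0.32), 0.06 for MYC and ribosome biogenesis genes (14 of 21 higher, 0.296, GAR1 0.30) and 0.02 for osteoblast and mesenchymal markers (11 of 19 higher, 0.244, COL6A3 0.35). Among the comparison lists, the median was -0.04 for epithelial markers (6 of 18 higher, camera adjusted p = 0.927, CLDN4 0.25), -0.01 for blood cell markers (7 of 16 higher, 0.740, CD4 -0.27) and 0.12 for reference genes (9 of 13 higher, 0.370, TBP -0.33).

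**Figure D3:**
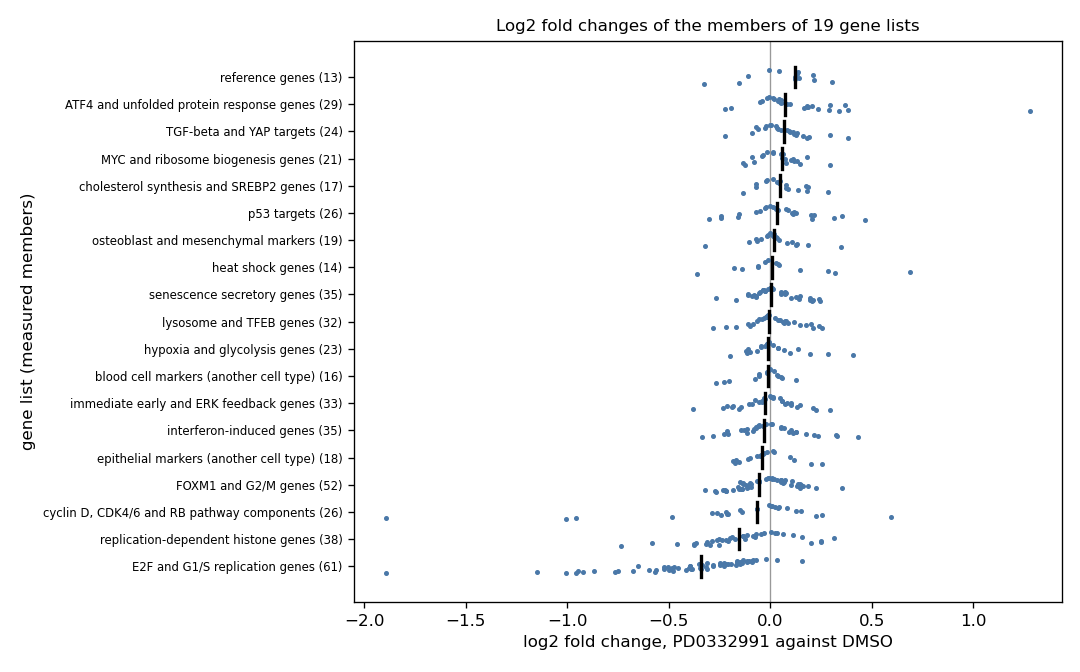
Log2 fold change of PD0332991 against DMSO (horizontal axis) for each measured member (point) of 19 gene lists (vertical axis, number of members in brackets), with the median of each list as a black bar. The E2F and G1/S list has the lowest median, -0.34, and 59 of its 61 points lie below 0.

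Over the 19 lists camera called 5 with the preset correlation and 0 with an estimated correlation, at which 5 had an unadjusted p under 0.05; fry, which tests whether the genes of a list move one way on balance, called 5. Regrouping the arrays gave 5 or more calls with the preset correlation in 36 of 100 splits, the real one included, so the number of calls alone is no larger than chance can give.

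The treatment effect did not differ detectably between the array sets. limma's interaction term passed 0 of 21980 probe sets (562 at an unadjusted p under 0.05, where 1099 would arise by chance), and its smallest adjusted p was 0.840. Across all probe sets the log2 fold changes of both sets had r = 0.03, and across the 917 probe sets with an unadjusted p under 0.05 in the joint fit, which were chosen on the same arrays, r = 0.73; genes are not independent replicates. The E2F and G1/S list gave an adjusted p of 0.876 for the interaction.

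One control array stood apart. DMSO replicate 1 correlated with the others at r = 0.958 to 0.967 across probe sets, where the remaining 9 arrays correlated at 0.972 to 0.991 among themselves, and its interquartile range was 3.18 against 3.32 to 3.68. Its mean over the E2F and G1/S list, 9.06, lay between the other DMSO arrays (9.18 to 9.45) and the treated arrays. No pair of arrays held identical values.

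**Figure D4:**
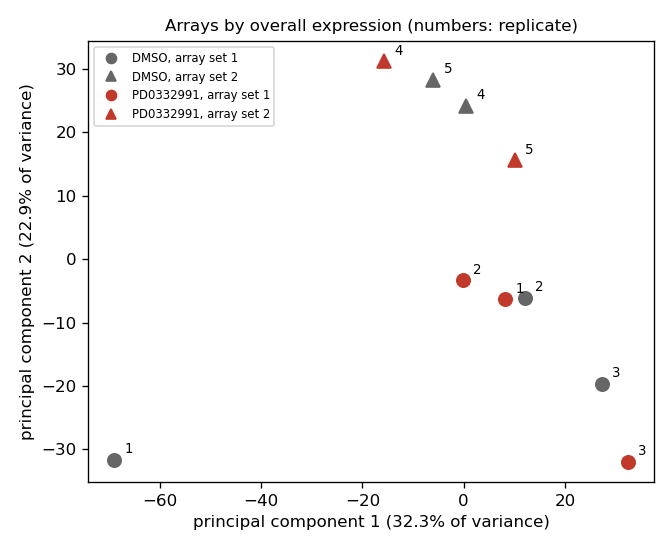
First and second principal components of the 10 arrays (32.3% and 22.9% of the variance), DMSO in grey and PD0332991 in red, circles for array set 1, triangles for array set 2, each point numbered by replicate. DMSO replicate 1 lies alone at the lower left, at -69.1 on the first component, and the array sets part along the second.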

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

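Of the tests in this part, those on level-dependent differences between arrays and on S-phase histone genes were chosen after the results were seen. Each of 82 measures in a group of 5 arrays was screened for an array far from the other 4. Chance picks out about 1 in 20, or 4.1 here, and 5 were found, 4 of them on DMSO replicate 1.

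The highest correlation of DMSO replicate 1 with another array was 0.967, far below the 0.989 to 0.991 of the other DMSO arrays. On this array the mean of the cholesterol synthesis and SREBP2 genes was 8.02 (others 8.44 to 8.58), that of the MYC and ribosome biogenesis genes 9.21 (9.53 to 9.62) and that of the reference genes 10.1 (10.5 to 10.6). The fifth value was CCNE1 on PD0332991 replicate 3, 9.41 where the other treated arrays held 9.10 to 9.18 and the DMSO arrays held 10.1 to 10.3.

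DMSO replicate 1 had lower values for abundant genes and a narrower range than the other arrays, so a compressed signal range is a candidate explanation of its distance. After cyclic loess, which removes level-dependent differences, its highest correlation was 0.970, still under the lowest among the other 9 arrays (0.971), which argues against compression as the whole cause, by a narrow margin. A treated culture under a DMSO label was also tested. Over the E2F and G1/S list this array lay 0.16 above the treated arrays of its set (95% bootstrap interval over genes 0.05 to 0.27). DMSO replicates 2 and 3 lay 0.45 above them (0.41 to 0.54). Both intervals resample the genes of the list and hold no spread between cultures. The DDIT4 value of DMSO replicate 1, 6.33, was at the DMSO level. The tables therefore argue against a swapped label, and a difference in RNA quality or in the culture stays open and untested.

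The fall of E2F and G1/S genes beside G2/M genes that did not pass is the pattern most tied to the design. For the fall of the E2F and G1/S genes, level-dependent array differences are argued against, since the median after cyclic loess was -0.37. For the G2/M genes they stay open: after cyclic loess the median was -0.08 and the list passed as lower by camera with the preset correlation (adjusted p = 0.00774), but not with an estimated correlation (adjusted p = 0.544) or by the exact permutation of array means (p = 0.40). The difference between the lists was -0.36 after cyclic loess (95% confidence interval -0.45 to -0.27, exact permutation p = 0.0167). That both lists fell alike is argued against by the same test on the deposited values (exact permutation p = 0.0167). A smaller share of cells in S phase remains open. The 23 histone genes above the median level of the table had a median of -0.17. Their median difference from the E2F and G1/S list, 0.165, pointed to a smaller fall of histones. Its bootstrap interval, 0.02 to 0.31, resamples genes and holds no spread between arrays, and the array means gave an exact permutation p of 0.0833. A direct response of E2F-driven transcription to the inhibitor, the explanation the design offers, is a hypothesis that cannot be told apart from fewer cells in S phase with these arrays.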

How the results depend on the processing

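Leaving out both arrays numbered 1, a threshold of 0.1, cyclic loess, leaving out shared list members or DDIT4, and the combinations with an estimated correlation were chosen after seeing the data. The 11 genes past the threshold kept their direction in all 274 values over 25 other settings and stayed past it in 165. The 57 other genes named kept their side and direction in 1409 of 1424 values; 14 values of CCNG2, YPEL2, PIK3IP1, CCND2, BARD1 and RBL1 passed in other settings, and RB1, uncalled, turned to 0.038 in array set 2. Array set 1 alone gave 0 higher and 0 lower genes, and array set 2 alone 0 and 0 and 2 lists, with fewer arrays in each. The fit without array set and the one centred on the array median each kept 1 higher gene, DDIT4. Single-symbol probe sets alone gave 4 higher and 14 lower genes, with fewer probe sets tested, and ANOVA without moderation 5 lower. The threshold of 0.1 gave 4 higher probe sets, 1 of them unnamed. Array weights, which gave DMSO replicate 1 a weight of 0.147, called 13 higher and 50 lower probe sets, not all of which are single-symbol genes. Camera with an estimated correlation called 0 lists, but 3 combined with quantile normalization or array weights, 4 with cyclic loess and 2 without both arrays numbered 1, the E2F and G1/S and histone lists each time. Combined with leaving out 1 array it called 2 without DMSO replicate 1 or PD0332991 replicate 3 and 0 in the other 8 fits. With the preset correlation 8 were called without both arrays numbered 1. The osteoblast and mesenchymal markers were among them, but did not pass there by camera with an estimated correlation (adjusted p = 0.273). No scaling moved the median of all genes by over 0.1 (-0.02 as deposited), and the interaction with array set passed 0 genes in each alternative run. Signals over background were not used here, so the dim genes' precision is known only from their spread.

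Replicate numbers did not pair the arrays throughout. Deviations from the group means of same-numbered arrays correlated at 0.04, 0.07, 0.54, 0.23 and 0.20 (-0.099, 0.018, 0.40, -0.35 and -0.27 after removing array set). For 2 of 5 numbers, 3 and 4, the treated array that best matched the DMSO array had the same number. Replicate 3 was highest by both measures, so a pairing of some arrays is not excluded. With the replicate block limma called 1 higher gene, DDIT4, 1 lower gene, FAM111B, and the same number of lists, 5.

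List medians that lost their call were, with an estimated correlation, -0.34 (E2F and G1/S), -0.15 (histones), -0.063 (RB pathway), 0.073 (ATF4) and 0.069 (TGF-beta and YAP), all without a change in the median by construction. The histone list lost it in set 1 (-0.15), the RB pathway, ATF4 and TGF-beta lists in set 2 (-0.026, 0.033 and 0.056), and the TGF-beta list after quantile normalization (0.054), cyclic loess (0.048) and array weights (0.043). Combined with an estimated correlation, calls were also lost by the ATF4 list after quantile normalization (0.066), with array weights (0.054) and without both arrays numbered 1 (0.053), by the RB pathway list without both (-0.065) and by the TGF-beta list in each of the 4 combinations (0.054, 0.048, 0.043 and 0.043), and the G2/M list passed in none. The RB pathway list turned to 0.0085 without shared members, since its lowest genes are E2F list members. The G2/M list gained a call after quantile normalization (-0.066), cyclic loess (-0.078), array weights (-0.11) and without both arrays numbered 1 (-0.049), and the senescence list with array weights (0.086) and without both arrays numbered 1 (0.059), both lost with an estimated correlation (adjusted p = 0.184 and 0.125). Apart from those named, the cause was not tested.

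The direction of uncalled lists turned, by the test, in these settings, with medians. Immediate early genes had -0.077 in set 1, -0.021 after quantile normalization, -0.018 after cyclic loess, -0.026 by fry and -0.027 without shared members. Hypoxia genes had -0.017 in set 2, -0.013 after quantile normalization, -0.037 after cyclic loess, -0.0086 by fry, 0.0013 with array weights and -0.018 without both arrays numbered 1. Lysosome genes had -0.031 in set 2, -0.0023 after cyclic loess, 0.011 with array weights and -0.021 without both arrays numbered 1. Epithelial markers had 0.045 in set 2, -0.030 after cyclic loess, 0.032 with array weights and 0.030 without both arrays numbered 1, and blood cell markers 0.033 in set 2, 0.033 after quantile normalization, 0.033 after cyclic loess, 0.12 with array weights and 0.074 without both. With array weights and without both arrays numbered 1, cholesterol genes had -0.033 and -0.050 and MYC genes -0.0020 and -0.034; reference genes had -0.0075 with array weights.

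Leaving out 1 array at a time gave 1 to 3 higher and 1 to 20 lower probe sets. It gave 4 to 7 lists with the preset correlation, 0 to 2 with an estimated one. The 20 came without DMSO replicate 1; 5 came without PD0332991 replicate 2 or 3. DDIT4 and E2F2 passed each time. Medians ran from -0.39 to -0.29 for the E2F and G1/S list, called each time with the preset correlation but in 2 of 10 fits with an estimated one (adjusted p = 0.0240 to 0.146), from -0.097 to 0.0065 for the G2/M list, -0.21 to -0.11 for histones, -0.10 to -0.036 for the RB pathway, 0.067 to 0.12 for ATF4 genes, 0.048 to 0.093 for TGF-beta and YAP targets and -0.026 to 0.067 for senescence genes. Among uncalled lists that turned, they ran from -0.057 to 0.040 (immediate early), -0.014 to 0.086 (cholesterol), -0.023 to 0.029 (lysosome), -0.031 to 0.086 (MYC), -0.037 to 0.023 (hypoxia), -0.11 to 0.053 (epithelial), -0.058 to 0.089 (blood cell) and 0.013 to 0.16 (reference genes).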

Other observations

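The FOXO list was tested with a prediction written before its result, and the other 6 lists and the splits within array sets were chosen after the first results were seen. Among the genes with the smallest p that were higher, named here after their values were seen, were CCNG2 (0.78 on the log2 scale, limma adjusted p = 0.0629), YPEL2 (1.03, 0.141) and PIK3IP1 (0.48, 0.207), beside SESN3. CCNG2 and SESN3 are known targets of the FOXO transcription factors. A list of other FOXO targets, without any gene already seen among the highest, was then tested. Of its 27 measured members 21 were higher, the median was 0.09 and the array means rose by 0.10 (95% confidence interval 0.06 to 0.13). The exact permutation p was 0.0167, the smallest possible, camera with a preset correlation gave p = 3.5e-04, and with an estimated correlation the adjusted p over 7 lists was 0.0359. Named after their values were seen, its members with the smallest p were PIK3R3 (0.60), TXNIP (0.33), KLF9 (0.34) and, lower, INSR (-0.26, limma unadjusted p = 0.0219). No member passed alone. A wider rise of FOXO targets after PD0332991 is therefore a hypothesis that these arrays are consistent with; it was found and tested on the same samples.

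Fanconi anaemia and homologous recombination genes were lower in 17 of 23 measured members (median -0.24, camera adjusted p = 5.9e-06 over 7 lists, adjusted p = 0.256 with an estimated correlation, exact permutation p = 0.117), among them, named after their values were seen, RAD51D at -0.29 and BARD1 at -0.40. Kinetochore and centromere genes were lower in 14 of 18 (median -0.09, camera adjusted p = 0.00145, adjusted p = 0.290 with an estimated correlation, exact permutation p = 0.200), and ZWINT (-0.43), HJURP (-0.37) and CENPM (-0.45), again named after their values were seen, passed adjusted over the list alone but not over all probe sets. All 13 aminoacyl-tRNA synthetase genes measured were higher (median 0.17, camera adjusted p = 5.9e-06, adjusted p = 0.290 with an estimated correlation, exact permutation p = 0.183), with no gene past the threshold. Condensin and cohesin genes (7 of 17 higher, median -0.00, camera adjusted p = 0.575), proteasome genes (16 of 24 higher, 0.03, 0.203) and splicing factor genes (11 of 18 higher, 0.05, 0.531) gave no call.

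The array groups were compared with 100 of the 126 ways to split 10 arrays into 5 and 5, the real split included. As many genes in 1 direction as the 2 higher genes came from 3 splits, and as many as the 9 lower genes from 2. Both shares are under 5%, but only 45 of the 100 splits keep treatment balanced in each array set. The others mix treatment with array set and give no fair chance rate. Of all 60 splits balanced in each array set only the real one gave 2 or more genes in 1 direction, and the highest other gave 1. Over these 60, chance is excluded at the 5% level for the count of 9 lower genes. For the 2 higher genes the margin was 2 against 1. SESN3, 1 of the 2, lost its call in 9 of the 10 fits that left out 1 array. Both directions also shared 1 adjustment, so chance is not called excluded for the higher count. Among the 100 splits the highest other gave 2783. It put DMSO replicate 1 with the 4 arrays of set 2, so with array set as a covariate it compares that array with the rest of its set. It therefore points to a structure of the samples inside set 1. The treatment comparison within either array set alone passed no gene, but that is another test. A difference of the E2F and G1/S list mean as large as the real 0.404 came from 2 splits, the highest other being 0.434; that other split exchanged DMSO replicate 1 and PD0332991 replicate 5. Within array sets the real split stood first of 60, with 0.380 as the highest other. Chance is therefore excluded at the 5% level for this list taken alone. As 1 of 19 lists, the tests differ. The adjusted p was 0.106 by the exact permutation within array sets and 0.0547 by camera with an estimated correlation. It was 0.00703 by fry and 3.0e-44 by camera with the preset correlation. The count of 5 called lists was reached by 36 splits, with 11 as the highest other, and by 22 of the 60 splits within array sets, with 9 as the highest other, so chance is not excluded for it.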
